A study of Solanum lycopersicum with 12 samples.

How the data were processed

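RNA of tomato fruit (cultivar Ailsa Craig) was sequenced in 12 libraries, from wild type (WT) and from slnor, a line carrying a CRISPR mutation in the NAC transcription factor gene NOR, at the breaker stage and 7 days later. Per the labels, each of the 4 groups has 3 libraries and the tissue is given only as fruit. Nothing in the labels says that the replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. The library kit, the strand setting, the genome build and the annotation are not given in the sources used here.

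The authors deposited a table of raw counts per gene, whole numbers with 1 column per library. HISAT, UMI-tools, StringTie and edgeR are named in the submitters' processing notes, with no version, order or role. Whether a count stands for a read or for a molecule collapsed by its identifier is not given in the sources used here. The authors also deposited 1 table per library in a unit inferred here to be FPKM, since the tables do not name it. Dividing the count by this value and by the library total gave the same gene length in all 12 libraries within 1% for 100% of the 7290 genes with at least 1000 counts in each. The columns summed to 663852 to 688291. The FPKM values served only for this check and for a check of gene length, and every test used the counts. All columns of per-sample values were used.

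The count table lists 34075 genes, of which 24155 had at least 1 count. Library totals ran from 50714230 to 69124795 counts, and 20191 to 21255 genes were detected per library. Replicate libraries were compared pair by pair. In all 12 pairs the counts differed by more than sampling noise (chi-square per degree of freedom 4.83 to 18.57), so none was treated as a duplicate.

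Tests were run in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest) on the counts as deposited, with TMM scaling, the filterByExpr low-count filter over the 4 groups and 1 fit of all 12 libraries. The filter kept 20070 genes holding 99.988% of the counts. TMM factors ran from 0.9474 to 1.0916 and the common biological coefficient of variation was 7.39%. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test over all genes tested, and a gene was called at an adjusted p under 0.05. The 5 comparisons were slnor against WT at each stage, the later against the earlier stage in each genotype, and the difference between the 2 stage changes (the interaction). Expression is given as CPM (counts scaled to a common library size with TMM) as mean ± SD with n = 3, and changes as log2 fold changes. Their standard error (SE) is the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic. A fold against a group with no count in any library is given as a lower bound, with 3 counts over the group's libraries in place of 0. Such bounds cover counting error only.

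The groups, the comparisons, the tests, the alternatives, 15 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover ripening transcription factors, ethylene synthesis, ethylene perception and response, carotenoid synthesis up to lycopene, carotenoid steps after lycopene, cell wall softening, cuticle, flavonoids and phenylpropanoids, glycoalkaloids, flavour volatiles, sugar, starch and acid metabolism, chlorophyll breakdown, abscisic acid, light harvesting, and seed markers. The cuticle, light-harvesting and seed lists also serve as markers of epidermis, green tissue and seed. Further lists defined by words in gene descriptions (heat shock, pathogenesis and seed storage among them) were not used here, since the tables used carry no descriptions. Each list was tested with camera (limma 3.58.1) with its preset inter-gene correlation of 0.01 on log2 CPM, which asks whether the members move together relative to all other genes tested, with adjustment over the 15 lists of a comparison. The rule names NOR, then in each list up to 3 members (genotype effects) or 2 members (stage changes and interaction) whose name was matched as described below. These had the largest change of at least 2-fold at an adjusted p under 0.05. No overlap of CPM between groups was also required, except for the interaction. Where a list had no such member, the member of highest mean CPM with a matched name was taken. In each of the 3 marker lists the member of highest mean CPM was taken too. Because the tables used name no genes outside the lists, at most 2 rising and 2 falling identifiers per comparison were taken by fold, with at least 10 CPM in the higher group.

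The files do not pair identifiers with gene names. Names and identifiers of the list members were paired from published nomenclature when the lists were fixed, 196 pairs in all, and 190 of these identifiers are in the count table. The pairs were checked against the RefSeq gene table of assembly SLM_r2.1 by chromosome and by rank along the chromosome. None of the count table's identifiers occurs in that gene table, so the check is indirect and no coordinates are given. Of 150 pairs whose name the gene table holds, 146 matched with a rank difference of at most 10% of the genes of the chromosome. The other 4 did not and were dropped. A further 46 had no such name, stayed in the list tests and are printed by identifier only. The tolerance was first 2%, which 139 pairs met, and was widened and 27 aliases added after the gene table was seen but before any fit. When names were paired with identifiers at random, a median of 4 and at most 10 pairs matched over 200 draws. Members of families of close copies, such as the chlorophyll a/b-binding, Rubisco small subunit, chalcone synthase, phenylalanine ammonia-lyase, lipoxygenase and ACC synthase genes, are uncertain as single genes, since counting may have split or shared their reads.

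The test was run on simulated counts with 200 changed genes drawn from the real means and library sizes. For the genotype effect at breaker, among 19705 genes, 64.2% of the genes changed 1.5-fold, 80.6% of those changed 2-fold and 80.3% of those changed 4-fold were recovered, and 12 of the 162 genes called were false. For the interaction, among 19693 genes, the recovered shares were 41.8%, 74.6% and 78.8%, with 16 false among 146 calls. The simulation changed far fewer genes than the 42.2% to 65.3% called in the data. It therefore does not test the scaling under such wide change. Alternatives were RLE factors or library totals alone in place of TMM, no low-count filter or a CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, each library left out in turn, an added 2-fold threshold, and for the lists an estimated correlation and fry. Checks of the lists with only the names matched in the gene table, and of the lists under library totals alone, were added after the data were seen.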

Results

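Fruit transcripts were counted in 12 tomato RNA-seq libraries, 3 each from wild type at breaker, slnor at breaker, wild type 7 days after breaker and slnor 7 days after breaker. Breaker is the stage at which a green fruit first shows a change of colour. The slnor line carries a CRISPR mutation in NOR, a NAC transcription factor gene needed for normal ripening. Library totals lay between 50714230 and 57552548 counts in wild type at breaker, 51414686 and 69124795 in slnor at breaker, 55352592 and 66795632 in wild type 7 days later, and 57880241 and 64580114 in slnor 7 days later. The 100 most abundant genes took 23.9% to 24.2% of the counts in every wild-type library and 19.3% to 20.4% in every slnor library. The ethylene-responsive fruit gene E8 (Solyc09g089580.4) was the most abundant transcript in wild type at breaker, at 1.72% to 1.73% of counts.

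On the first principal component, which held 46.6% of the variance of log2 CPM, the wild-type libraries moved from between −61.8 and −61.3 at breaker to between 107 and 112 after 7 days. The slnor libraries moved from between −73.1 and −68.8 to between 22.6 and 24.2. The second component held 23.1% and set all 6 slnor libraries (37.7 to 58.8) apart from all 6 wild-type libraries (−71.7 to −24.9).

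**Figure D1:**
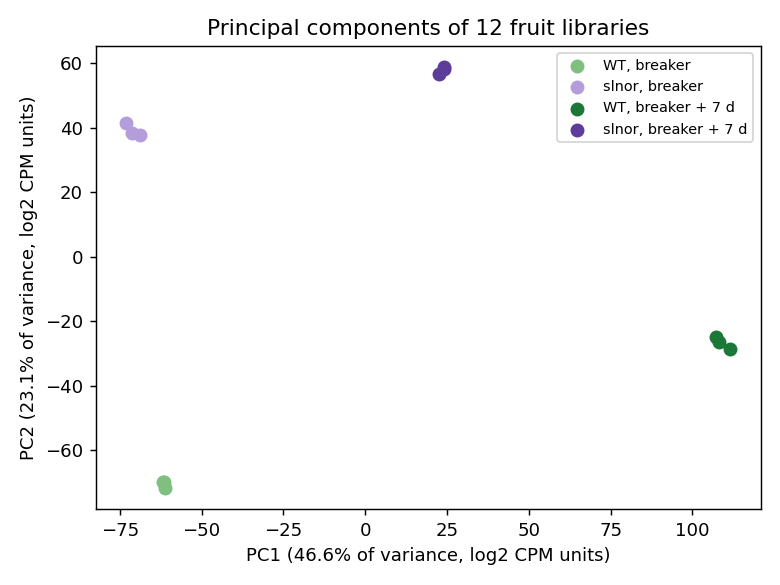
Scores of the 12 libraries on the first (x) and second (y) principal component of log2 CPM, 1 point per library, coloured by genotype and stage. The 3 wild-type libraries taken 7 days after breaker lie above 107 on the first component, and the 3 slnor libraries of that stage lie between 22.6 and 24.2.

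The transcript of the mutated gene NOR (Solyc10g006880.3) was present in all 12 libraries. At breaker it stood at 978, 970 and 955 CPM in the wild-type libraries and at 776, 792 and 896 CPM in the slnor libraries, a log2 fold change of −0.24 (SE 0.048, adjusted p = 5.63e-04). With library totals alone in place of TMM this change was −0.06 (adjusted p = 0.281), so the lower level at breaker depends on the scaling. After 7 days the libraries stood at 459, 480 and 467 CPM in wild type and at 553, 577 and 515 CPM in slnor, and the log2 fold change was 0.23 (SE 0.048, adjusted p = 7.05e-04). NOR fell with stage in both genotypes, by 1.05 on the log2 scale in wild type and by 0.58 in slnor. A small mutation need not change the amount of transcript, so these levels do not check the genotype.

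The first comparison asked how slnor fruit differed from wild type at breaker. PG2a (Solyc10g080210.2), the fruit polygalacturonase that degrades pectin, stood at 6672 ± 309 CPM in wild type and 237 ± 12 in slnor (28.2-fold lower). MAN4a (Solyc01g008710.5.1), an endo-mannanase, stood at 1442 ± 55.1 against 57.5 ± 11.6 CPM (25.1-fold lower), and the beta-galactosidase gene TBG4 (Solyc12g008840.2) at 500.5 ± 29.9 against 22.9 ± 0.764 CPM (21.9-fold lower). In the flavonoid pathway, the chalcone synthase gene CHS1 (Solyc09g091510.3) stood at 995 ± 33.8 against 116 ± 19.7 CPM and its regulator MYB12 (Solyc01g079620.4) at 75.7 ± 5.17 against 11.6 ± 1 CPM.

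At breaker, 13 of the 17 cell wall genes tested fell in slnor, 3 rose and 1 did not pass. As a list they fell relative to the other genes (camera adjusted p = 7.01e-05, adjusted p = 0.0713 with an estimated correlation). With library totals alone, 10 of the 17 fell. The log2 fold changes were −4.82 for PG2a (SE 0.042, adjusted p = 7.57e-21), −4.65 for MAN4a (SE 0.106) and −4.45 for TBG4 (SE 0.052). All 11 genes of carotenoid synthesis up to lycopene, the red pigment of ripe fruit, fell (camera adjusted p = 7.90e-08, adjusted p = 0.128 with an estimated correlation), and 9 of the 11 did so with library totals alone. GGPS2 (Solyc04g079960.1), a geranylgeranyl diphosphate synthase gene, fell 5.29-fold from 123 ± 6.55 to 23.2 ± 1.84 CPM, and ZISO (Solyc12g098710.2), the zeta-carotene isomerase gene, fell 2.30-fold. Of the 10 genes of carotenoid steps after lycopene, 5 fell and 3 rose (camera adjusted p = 0.217). VDE (Solyc04g050930.3), BCH2 (Solyc03g007960.3) and CrtR-b1 (Solyc06g036260.3), which act in the formation or conversion of xanthophylls, were among those that fell. Their log2 fold changes were −1.42, −1.24 and −1.03.

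Flavonoid and phenylpropanoid genes fell most as a group at breaker. Of 12 genes, 10 fell and 2 rose, with a median log2 fold change of −1.93 (camera adjusted p = 2.31e-08, adjusted p = 0.0713 with an estimated correlation). CHS1 (−3.10, SE 0.084), CHS2 (Solyc05g053550.3, −3.05, SE 0.078) and MYB12 (−2.71, SE 0.084) led them, the chalcone synthase copies being uncertain as single genes. Among 8 cuticle genes, 5 fell and 3 rose (camera adjusted p = 0.0212, adjusted p = 0.132 with an estimated correlation, 0.0646 without wild-type replicate 1 of the later stage, and 0.230 over checked names only). The most abundant member over all 12 libraries, Solyc03g065250.4, fell from 245 ± 7.47 to 101 ± 5.73 CPM. CER6 (Solyc02g085870.3), which elongates wax fatty acids, fell 4.10-fold from 292 ± 7.43 to 71.2 ± 2.75 CPM, while the cutin genes CD1 (Solyc11g006250.2) and GPAT6 (Solyc09g014350.3), both under 3 CPM, rose 3.49-fold and 2.87-fold. Light-harvesting genes, also markers of green tissue, fell in 15 of 20 cases and rose in 1 (camera adjusted p = 9.77e-05, adjusted p = 0.128 with an estimated correlation). Their most abundant member over all 12 libraries, PSBO (Solyc02g065400.3), a photosystem subunit gene, fell from 260 ± 10.6 to 182 ± 5.25 CPM, and the Rubisco small subunit gene RBCS-2A (Solyc03g034220.3) was the one that rose, from 222 ± 6.92 to 284 ± 19.1 CPM.

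Among 15 ripening transcription factor genes, 10 fell and 5 rose at breaker (camera adjusted p = 0.0174, adjusted p = 0.175 with an estimated correlation), and 8 fell with library totals alone. FUL1 (Solyc06g069430.3), a MADS-box gene, stood at 585 ± 12.6 CPM in wild type and 231 ± 14.5 in slnor, and AP2a (Solyc03g044300.3) at 525 ± 4.58 against 219 ± 3.72. NAC1 (Solyc04g009440.3) rose 6.16-fold, from 6.42 ± 0.31 to 39.7 ± 3.78 CPM. RIN (Solyc05g012020.4) and PSY1 (Solyc03g031860.3) are outside the naming rule and were chosen after their values were seen. RIN fell by 1.06 and PSY1, the fruit phytoene synthase gene, by 0.87 on the log2 scale. Ethylene synthesis genes went both ways, with 4 of 10 falling and 3 rising (camera adjusted p = 0.272). ACS2 (Solyc01g095080.3), an ACC synthase gene, fell 3.82-fold from 867 ± 15 to 227 ± 20.2 CPM, whereas ACO5 (Solyc07g026650.3) rose 6.74-fold from 17.6 ± 1.33 to 119 ± 27.8 CPM. ACS3 (Solyc02g091990.3) had no count in wild type and 0.594 ± 0.324 CPM in slnor, at least 31-fold higher. In ethylene perception and response, 5 of 16 genes rose and 5 fell (camera adjusted p = 0.471), or 8 and 4 with library totals alone. The ripening gene E4 (Solyc03g111720.3) fell 2.22-fold from 5374 ± 178 CPM.

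Flavour volatile genes fell in 8 of 13 cases and rose in 3 at breaker (camera adjusted p = 0.0212, adjusted p = 0.128 with an estimated correlation, and 0.154 over checked names only). The lipoxygenase gene LOXC (Solyc01g006540.4), which supplies short-chain lipid volatiles, fell 17.4-fold from 1323 ± 52.5 to 75.8 ± 15.3 CPM. LOXD (Solyc03g122340.3) and the aromatic amino acid decarboxylase gene AADC1A (Solyc08g068680.4) rose 4.33-fold and 4.12-fold. Of 5 chlorophyll breakdown genes, 3 fell and 1 rose (camera adjusted p = 0.0247, adjusted p = 0.298 with an estimated correlation, and 0.0597 with library totals alone). SGR1 (Solyc08g080090.3), the stay-green gene, fell 2.58-fold from 1122 ± 25.7 to 435 ± 46.1 CPM. Sugar, starch and acid genes rose in 5 of 12 cases, or 8 with library totals alone, and fell in 2 (camera adjusted p = 0.138), with the sucrose synthase gene SUS1 (Solyc12g009300.3) rising 2.03-fold from 27.9 ± 2.68 CPM. Abscisic acid genes rose in 2 of 4 cases and fell in 1 (camera adjusted p = 0.272), with CYP707A2 (Solyc08g005610.3), an abscisic acid hydroxylase gene, rising 2.40-fold. None of the 8 glycoalkaloid genes passed the edgeR test at breaker with TMM, and 2 rose with library totals alone (camera adjusted p = 0.857 with TMM). The most abundant of them with a checked name, GAME11 (Solyc07g043420.3), stood at 19.1 ± 0.562 and 17.6 ± 0.662 CPM. Of 5 seed markers, 1 rose and 1 fell (camera adjusted p = 0.80), the one that fell being the most abundant, Solyc06g060840.1, at 70.5 CPM in wild type and 6.68 CPM in slnor.

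In total, 5142 genes were higher and 4758 lower in slnor at breaker, 49.3% of the 20070 tested, and 1301 and 937 of them changed at least 2-fold. Scaling by library totals alone gave 8447 higher and 2836 lower (74.9% higher, against 51.9% with TMM) and moved the median log2 fold change of all genes to 0.20, so the split into higher and lower genes rests on the scaling. Beyond the lists for which it is given above, that scaling moved the rising or falling count of a list by at most 1 gene. Among identifiers outside the lists, Solyc01g081250.3 had no count in wild type and 84.7 ± 19.7 CPM in slnor (at least 4420-fold higher), and Solyc08g083190.3 stood at 22.5 ± 1.38 CPM in wild type with no count in slnor (at least 1440-fold lower). Adjusted over the list alone, the counts of the 15 lists were those given above, except that 6 rather than 5 genes of ethylene perception and response fell. The mean and the test differed in sign for ethylene synthesis (mean 0.75, test downward) and for seed markers (mean 0.30, test downward), and for glycoalkaloid genes the median (0.08) lay above 0 with the mean (−0.06) and the test below it.

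**Figure D2:**
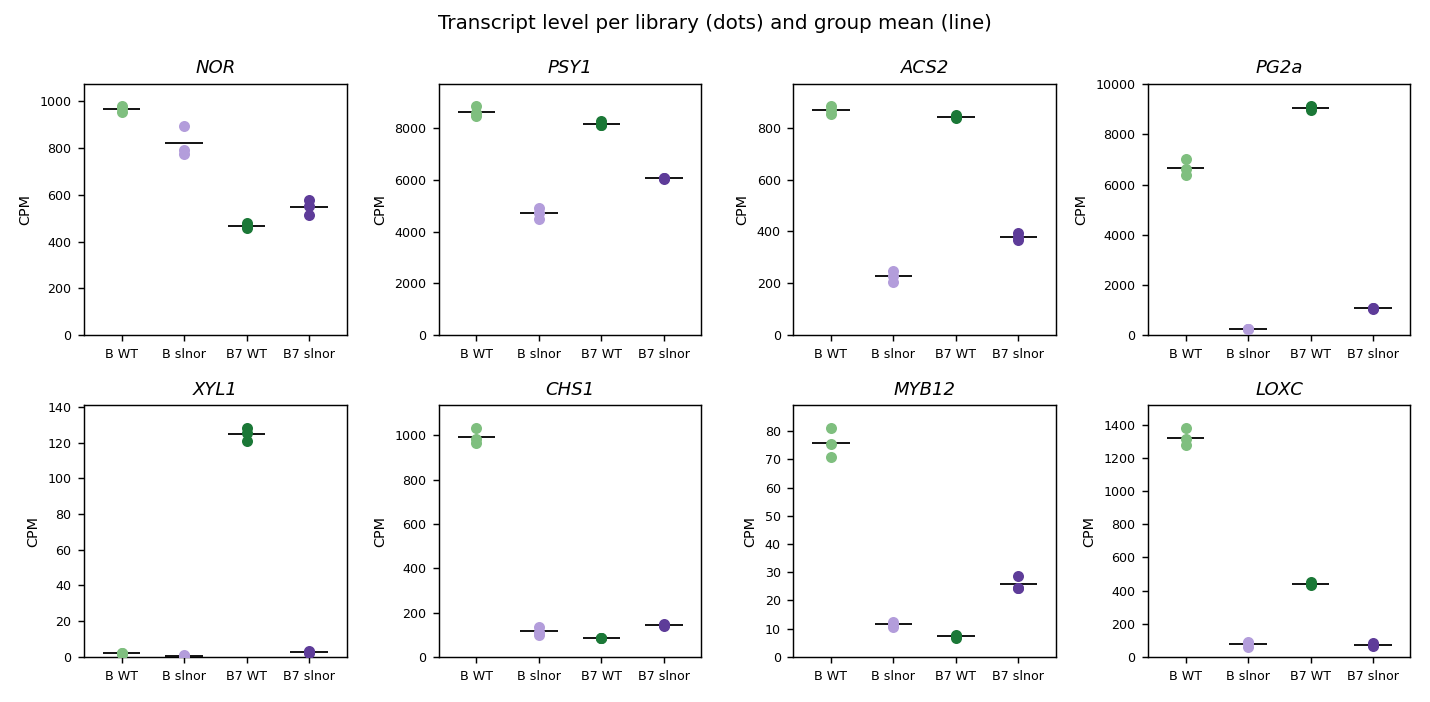
CPM of NOR, PSY1, ACS2, PG2a, XYL1, CHS1, MYB12 and LOXC (1 panel each, linear y axis from 0) in the 4 groups on the x axis, with 1 point per library and a line at the mean of 3. PG2a stays far below wild type in slnor at both stages (237 and 1063 against 6672 and 9056 CPM), whereas MYB12 in slnor lies below wild type at breaker and above it after 7 days.

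The second comparison asked how the genotypes differed 7 days after breaker. Several cell wall genes and the volatile gene LOXC, with deficits at breaker, were still low. MAN4a lay nearer to wild type, with a log2 fold change of −1.16 against −4.65 at breaker. PG2a stood at 9056 ± 82.3 CPM in wild type and 1063 ± 19.6 in slnor (8.52-fold lower), CEL2 (Solyc09g010210.3), an endo-glucanase gene, at 1364 ± 14.9 against 175 ± 4.96 CPM (7.80-fold lower), and LOXC at 441 ± 8.42 against 73.5 ± 9.81 CPM (5.99-fold lower). XYL1 (Solyc10g047030.3) stood at 125 ± 3.64 against 2.75 ± 0.649 CPM (45.1-fold lower). Flavonoid genes, in contrast, were higher in slnor, with MYB12 at 25.7 ± 2.4 CPM against 7.33 ± 0.645 and F3H (Solyc02g083860.3), a flavanone hydroxylase gene, at 142 ± 4.57 against 49 ± 3.56 CPM.

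Of the 12 flavonoid and phenylpropanoid genes, 10 rose in slnor relative to wild type at this stage and 2 fell, with a median log2 fold change of 1.11 (camera adjusted p = 7.96e-05, adjusted p = 0.241 with an estimated correlation). MYB12 (1.81, SE 0.088), F3H (1.54, SE 0.054) and the phenylalanine ammonia-lyase gene PAL3 (Solyc09g007920.4, 1.48, SE 0.040) had the largest rises of those with a checked name. Cuticle genes rose in 7 of 8 cases and the other did not pass (camera adjusted p = 1.04e-04, adjusted p = 0.0841 with an estimated correlation, and 0.0697 over checked names only). CD1 rose from 0.0254 ± 0.044 to 4.42 ± 0.54 CPM and GPAT6 5.82-fold to 1.74 ± 0.26 CPM. Of the 11 genes of carotenoid synthesis up to lycopene, 10 were lower in slnor and 1 higher (camera adjusted p = 7.96e-05, adjusted p = 0.248 with an estimated correlation). GGPS2 stood at 71.5 ± 1.51 against 10.7 ± 0.913 CPM, a fall by 2.75 on the log2 scale (SE 0.067).

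For the other 12 lists the camera adjusted p 7 days after breaker was 0.0588 or more. Light-harvesting genes rose in 10 of 20 cases and fell in 4 (camera adjusted p = 0.0588, and 0.0344 without wild-type replicate 3 or 0.0428 without wild-type replicate 1 of this stage, 0.0498 without slnor replicate 1 at breaker). RBCS-2A stood at 61.6 ± 2.65 CPM in slnor against 21.8 ± 0.823 in wild type, and Cab-1A (Solyc02g070940.1) at 5.78 ± 0.566 against 2.31 ± 0.157. Glycoalkaloid genes rose in 4 of 8 cases and the others did not pass (camera adjusted p = 0.0867). GAME12 (Solyc12g006470.2) rose 8.60-fold to 6.91 ± 0.815 CPM, GAME1 (Solyc07g043490.1) 7.72-fold to 0.702 ± 0.245 CPM and GAME11 4.58-fold to 2.17 ± 0.113 CPM. In sugar, starch and acid metabolism, 6 of 12 genes rose and 2 fell (camera adjusted p = 0.0867). The granule-bound starch synthase gene GBSS1 (Solyc08g083320.4) rose 4.02-fold from 29.6 ± 1.38 to 119 ± 2.21 CPM, SUS1 3.09-fold, and AGPL1 (Solyc01g109790.3), under 2 CPM, 2.72-fold. Abscisic acid genes rose in 3 of 4 cases (camera adjusted p = 0.0867), with NCED2 (Solyc08g016720.1) at 8.62 ± 0.839 against 2.84 ± 0.151 CPM. Carotenoid genes after lycopene rose in 5 of 10 cases and fell in 1 (camera adjusted p = 0.122), and LCY1 (Solyc04g040190.1), a lycopene cyclase gene, rose 2.71-fold to 25.6 ± 0.716 CPM.

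Cell wall genes divided, with 8 of 17 lower in slnor and 7 higher 7 days after breaker (camera adjusted p = 0.403). Flavour volatile genes fell in 8 of 13 cases and rose in 3 (camera adjusted p = 0.0988). LOXC was lower in slnor, whereas LOXA (Solyc08g014000.3) rose 4.38-fold to 1156 ± 80.8 CPM. Ethylene synthesis genes fell in 5 of 10 cases and rose in 4 (camera adjusted p = 0.403), with ACS2 at 379 ± 13.7 against 843 ± 5.7 CPM, ACO5 at 53.7 ± 2.45 against 9.31 ± 0.535 CPM, and ACS3 at least 29.2-fold higher than a wild-type group with no count. Ethylene perception and response genes rose in 9 of 16 cases and fell in 5 (camera adjusted p = 0.413), and the abundant E8 fell 1.35-fold from 11210 ± 156 CPM. Ripening transcription factor genes rose in 7 of 15 cases and fell in 5 (camera adjusted p = 0.505). GLK2 (Solyc10g008160.3), a regulator of chloroplast development, rose 3.55-fold to 1.42 ± 0.281 CPM. Chlorophyll breakdown genes rose in 2 of 5 cases and fell in 2 (camera adjusted p = 0.337), and SGR1 stood at 468 ± 26.8 against 1135 ± 21.7 CPM. Seed markers rose in 1 of 5 cases and fell in 2 (camera adjusted p = 0.403), with Solyc06g060840.1 at 0.417 CPM in slnor and 15 CPM in wild type.

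In all, 5711 genes were higher and 5496 lower in slnor 7 days after breaker, 55.8% of those tested, of which 2005 and 925 changed at least 2-fold. With library totals alone, 7068 were higher and 3932 lower (64.2% higher, against 50.96% with TMM), and the median log2 fold change of all genes was 0.10. Falling genes then numbered 3 rather than 5 in ethylene perception and response and 2 rather than 4 in light harvesting, and the other list counts moved by at most 1. Outside the lists, Solyc03g121600.4 stood at 15.6 ± 1.87 CPM in slnor against 0.0508 ± 0.088 in wild type, and Solyc03g095880.1 at 0.0475 ± 0.0249 against 10.1 ± 0.238 CPM. Adjusted over the list alone, 1 abscisic acid gene also fell, 2 rather than 1 of the carotenoid genes after lycopene fell, and 4 rather than 3 flavour volatile genes rose, with all other counts as given. The mean for ethylene synthesis (0.78) differed in sign from its median (−0.18) and its downward test.

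**Figure D3:**
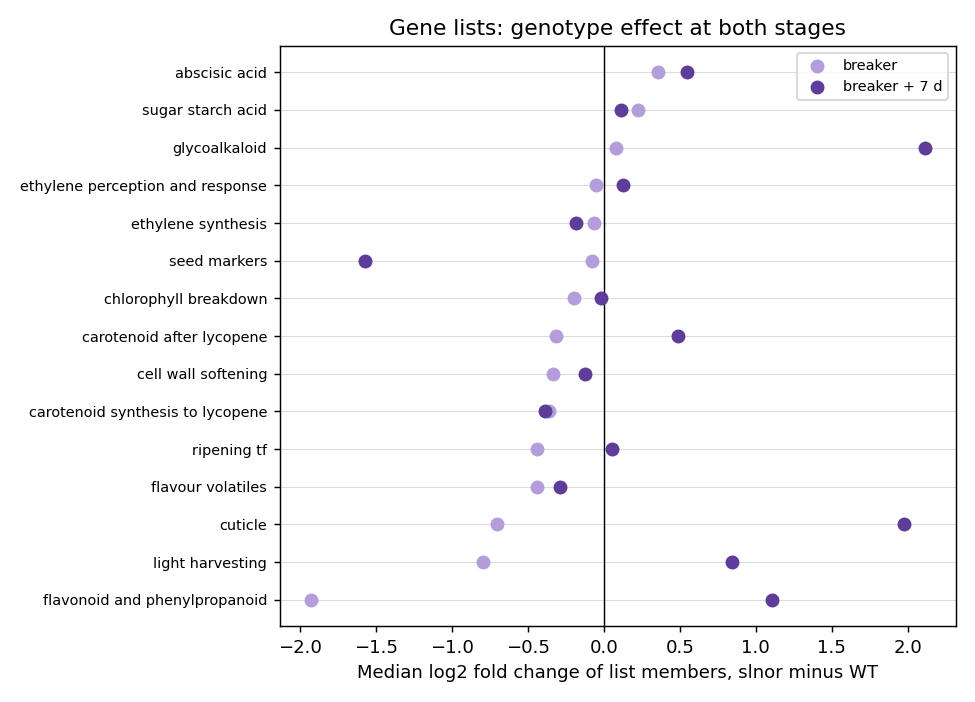
Median log2 fold change of slnor against wild type (x axis) over the tested members of each of the 15 gene lists (y axis), with 1 point for breaker and 1 for 7 days later. The flavonoid list moves from −1.93 to 1.11 and the cuticle list from −0.70 to 1.98, whereas carotenoid synthesis up to lycopene stays at −0.36 and −0.39.

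The third comparison described 7 days of ripening in wild type. Genes of the photosynthetic apparatus and of flavonoid and cuticle synthesis fell. PSBQ (Solyc02g079950.3), a photosystem subunit gene named here by the rule for slnor, stood at 304 ± 17 CPM at breaker and 10.8 ± 1.85 CPM after 7 days. CHS1 dropped from 995 ± 33.8 to 85.7 ± 1.22 CPM (11.6-fold), F3H from 694 ± 31.3 to 49 ± 3.56 CPM (14.2-fold) and CER6 from 292 ± 7.43 to 59.7 ± 1.36 CPM (4.89-fold). XYL1 rose 58.5-fold, from 2.13 ± 0.296 to 125 ± 3.64 CPM.

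All 20 light-harvesting genes fell in wild type (camera adjusted p = 1.48e-09, adjusted p = 0.0362 with an estimated correlation). CAB5 (Solyc12g006140.2) went from 2.61 ± 0.459 CPM to no count, at least 154-fold lower, and Cab-3C (Solyc03g005780.3) from 1.97 ± 0.494 to 0.0373 ± 0.0331 CPM. Cuticle genes fell in 7 of 8 cases and none rose (camera adjusted p = 4.38e-05, adjusted p = 0.0362 with an estimated correlation), with CER6 at −2.29 (SE 0.039) and CD1 at −4.91 (SE 0.538). Flavonoid genes fell in 11 of 12 cases and rose in 1 (camera adjusted p = 4.95e-08, adjusted p = 0.0581 with an estimated correlation). Glycoalkaloid genes fell in 7 of 8 cases and rose in 1 (camera adjusted p = 0.0219, adjusted p = 0.186 with an estimated correlation). GAME18 (Solyc07g043500.1) went from 2.52 ± 1.07 to 0.057 ± 0.0502 CPM, and GAME4 (Solyc12g006460.2) from 0.506 ± 0.143 CPM to no count, at least 29.9-fold lower. Ripening transcription factor genes fell in 11 of 15 cases and rose in 3 (camera adjusted p = 0.0118, adjusted p = 0.197 with an estimated correlation), with GLK2 falling by 2.51 on the log2 scale (SE 0.329) and NAC1 rising by 1.76 (SE 0.092).

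The other lists did not pass in wild type. Carotenoid synthesis up to lycopene rose in 6 of 11 cases and fell in 3 (camera adjusted p = 0.0788), and PSY1 stayed near its breaker level at 8627 ± 192 and 8165 ± 99.6 CPM (log2 fold change −0.08, adjusted p = 0.021, a call lost without wild-type replicate 1 at breaker or without wild-type replicate 2 or 3 after 7 days). Genes after lycopene fell in 6 of 10 cases and rose in 3 (camera adjusted p = 0.472), including the lycopene epsilon-cyclase gene CRTL-E-1 (Solyc12g008980.3), which went from 2.38 ± 0.346 to 0.0421 ± 0.073 CPM, and VDE, which fell 4.08-fold. Cell wall genes fell in 10 of 17 cases and rose in 7 (camera adjusted p = 0.166), MAN4a falling 16.9-fold from 1442 ± 55.1 to 85.2 ± 0.632 CPM. In ethylene synthesis, 6 of 10 genes fell and 2 rose (camera adjusted p = 0.0788, and 0.0476 without slnor replicate 2 at breaker). The ACC oxidase gene ACO6 (Solyc02g036350.3) fell 14.3-fold from 1317 ± 10.7 CPM, and ACS8 (Solyc03g043890.3) went from no count to 0.352 ± 0.0454 CPM, at least 18.4-fold higher. Ethylene perception and response genes fell in 8 of 16 cases and rose in 3 (camera adjusted p = 0.0788), with ETR6 (Solyc09g089610.3), an ethylene receptor gene, and E4 falling 2.28-fold and 2.15-fold. Flavour volatile genes fell in 7 of 13 cases and rose in 4 (camera adjusted p = 0.421), LOXA falling 4.49-fold. Sugar, starch and acid genes fell in 6 of 12 cases and rose in 4 (camera adjusted p = 0.454), GBSS1 falling 3.18-fold. Chlorophyll breakdown genes fell in 3 of 5 cases and rose in 1 (camera adjusted p = 0.498), and SGR1 did not pass (log2 fold change 0.02, adjusted p = 0.820). Abscisic acid genes fell in 2 of 4 cases and rose in 1 (camera adjusted p = 0.693), with NCED1 (Solyc07g056570.1) falling 2.48-fold from 452 ± 19 CPM. Seed markers fell in 2 of 5 cases and rose in 1 (camera adjusted p = 0.818).

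Across all genes, 6659 rose and 6449 fell between the stages in wild type, 65.3% of those tested, and 1406 and 2922 of them changed at least 2-fold. Outside the lists, Solyc12g150125.1 went from no count to 20.4 ± 1.75 CPM (at least 1070-fold higher) and Solyc05g056050.3 from 10.4 ± 1.97 to 0.0211 ± 0.0365 CPM. Adjusted over the list alone, 2 rather than 1 of the abscisic acid genes rose and the other lists kept their counts. For the seed markers the median (1.96) and mean (0.63) lay above 0 and the test pointed downward.

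The fourth comparison described the same 7 days in slnor. Several ripening genes that were low at breaker rose. PG2a went from 237 ± 12 to 1063 ± 19.6 CPM (4.49-fold), FUL1 from 231 ± 14.5 to 698 ± 7.62 CPM (3.02-fold) and ZISO from 616 ± 33.2 to 1693 ± 37.5 CPM (2.75-fold). ADH2 (Solyc06g059740.4), an alcohol dehydrogenase gene of volatile synthesis, rose 3.20-fold from 2148 ± 78.6 to 6877 ± 90.5 CPM.

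Carotenoid synthesis up to lycopene rose in 8 of 11 cases and fell in 1 in slnor (camera adjusted p = 8.68e-04, adjusted p = 0.541 with an estimated correlation), the one that fell being GGPS2 (2.17-fold, from 23.2 ± 1.84 to 10.7 ± 0.913 CPM). Light-harvesting genes fell in 13 of 20 cases and rose in 1 (camera adjusted p = 2.41e-05, adjusted p = 0.317 with an estimated correlation), with PSBQ going from 145 ± 8.36 to 20.6 ± 0.684 CPM and CAB5 from 0.997 ± 0.151 CPM to no count, at least 61.9-fold lower. No other list passed. Cell wall genes fell in 9 of 17 cases and rose in 8 (camera adjusted p = 0.948), XYL1 rising 4.96-fold to 2.75 ± 0.649 CPM. Carotenoid genes after lycopene rose in 5 of 10 cases and fell in 3 (camera adjusted p = 0.195, and 0.0385 over checked names only), with BCH2 rising 2.32-fold. Flavonoid genes rose in 6 of 12 cases and fell in 5 (camera adjusted p = 0.544), CHS2 rising 3.11-fold to 297 ± 13.9 CPM and MYB12 2.22-fold. Cuticle genes rose in 3 of 8 cases and fell in 1 (camera adjusted p = 0.544), with CER6 rising 1.5-fold.

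Ripening transcription factor genes rose in 7 of 15 cases and fell in 6 in slnor (camera adjusted p = 0.704), NAC1 falling 3.41-fold from 39.7 ± 3.78 to 11.6 ± 0.273 CPM. Ethylene synthesis genes fell in 6 of 10 cases and rose in 3 (camera adjusted p = 0.112), with ACO6 falling 6.53-fold and ACS8 going from no count to 0.319 ± 0.0928 CPM, at least 20.4-fold higher. Ethylene perception and response genes fell in 9 of 16 cases and rose in 5, or 10 and 3 with library totals alone (camera adjusted p = 0.333), E8 falling 1.22-fold. Glycoalkaloid genes fell in 6 of 8 cases and rose in 1 (camera adjusted p = 0.145, and 0.02 over checked names only), with GAME18 going from 3.17 ± 0.996 to 0.237 ± 0.092 CPM. Flavour volatile genes fell in 7 of 13 cases and rose in 4 (camera adjusted p = 0.704), AADC1A falling 3.45-fold. Sugar, starch and acid genes rose in 5 of 12 cases and fell in 4 (camera adjusted p = 0.913), the beta-amylase gene BAM1 (Solyc09g091030.3) rising 2.73-fold to 201 ± 3.46 CPM. Chlorophyll breakdown genes fell in 2 of 5 cases and rose in 1 (camera adjusted p = 0.90), abscisic acid genes fell in 1 of 4 and rose in 1 (camera adjusted p = 0.90), and seed markers fell in 2 of 5 with none rising (camera adjusted p = 0.397).

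Between the stages in slnor, 5261 genes rose and 5212 fell, 52.2% of those tested, and 833 and 1743 changed at least 2-fold. Library totals alone gave 3911 rising and 6754 falling (36.7% rising, against 50.2%). Outside the lists, Solyc02g072370.1 rose from 0.110 ± 0.102 to 11.8 ± 1.16 CPM and Solyc05g006220.3 fell from 23.6 ± 4.58 to 0.150 ± 0.209 CPM. Adjusted over the list alone, 6 rather than 5 carotenoid genes after lycopene rose, with the other counts as given. Median and mean differed in sign for carotenoid genes after lycopene, cell wall, ethylene synthesis, chlorophyll breakdown and abscisic acid genes, none of which passed.

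The fifth comparison tested whether the stage change differed between the genotypes. A positive interaction means that the later stage minus breaker was higher in slnor than in wild type, and equally that slnor stood higher relative to wild type after 7 days than at breaker. MYB12 (4.51, SE 0.121), CHS2 (3.93, SE 0.106) and CER6 (2.88, SE 0.054) had large positive interactions, since they fell in wild type and rose in slnor. MAN4a also had one (3.49, SE 0.138), with a steep fall in wild type from a level that slnor did not have at breaker. NAC1 (−3.52, SE 0.125) and XYL1 (−3.56, SE 0.353) had negative ones, NAC1 rising in wild type and falling in slnor, and XYL1 rising 58.5-fold in wild type against 4.96-fold in slnor.

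Among lists, flavonoid genes had a positive interaction in 11 of 12 cases and a negative one in 1 (camera adjusted p = 3.80e-13, adjusted p = 0.0176 with an estimated correlation). Cuticle genes were positive in 7 of 8 cases with none negative (camera adjusted p = 5.65e-08, adjusted p = 0.0158 with an estimated correlation), CD1 at 5.68 (SE 0.603). Light-harvesting genes were positive in 16 of 20 cases with none negative (camera adjusted p = 1.33e-08, adjusted p = 0.0265 with an estimated correlation), including Cab-1A at 2.95 (SE 0.169) and Cab-3C at 4.88 (SE 1.442). Ripening transcription factor genes were positive in 14 of 15 cases and negative in 1, NAC1 (camera adjusted p = 5.65e-08, adjusted p = 0.0176 with an estimated correlation), with GLK2 at 2.71 (SE 0.443). Cell wall genes were positive in 10 of 17 cases and negative in 3 (camera adjusted p = 9.99e-05, adjusted p = 0.0265 with an estimated correlation). Carotenoid genes after lycopene were positive in 5 of 10 cases with none negative (camera adjusted p = 0.00422, adjusted p = 0.130 with an estimated correlation), VDE at 1.89 (SE 0.109) and BCH2 at 1.36 (SE 0.084).

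The remaining lists did not pass the interaction test. Carotenoid synthesis up to lycopene was positive in 3 of 11 cases and negative in 3 (camera adjusted p = 0.363), PSY1 being positive at 0.44 (SE 0.040). Glycoalkaloid genes were positive in 3 of 8 cases with none negative (camera adjusted p = 0.0603, and 0.0464 with library totals alone, 0.0403 over checked names only or 0.0295 to 0.0416 without 1 of the wild-type libraries of the later stage), GAME12 at 2.89 (SE 0.258) and GAME1 at 2.74 (SE 0.632). Ethylene perception and response genes were positive in 9 of 16 cases and negative in 2 (camera adjusted p = 0.0603, and 0.0257 without slnor replicate 2 or 0.0434 without wild-type replicate 1 at breaker). Sugar, starch and acid genes were positive in 6 of 12 cases and negative in 2 (camera adjusted p = 0.108), GBSS1 at 1.33 (SE 0.057). Flavour volatile genes were positive in 5 of 13 cases and negative in 3 (camera adjusted p = 0.207), with LOXA at 1.97 (SE 0.073) and AADC1A at −1.68 (SE 0.221). Ethylene synthesis was positive in 4 of 10 cases and negative in 3 (camera adjusted p = 0.721), ACO6 at 1.13 (SE 0.091). Chlorophyll breakdown was positive in 2 of 5 cases with none negative (camera adjusted p = 0.453), abscisic acid in 2 of 4 with 1 negative (camera adjusted p = 0.481), NCED1 at 0.52 (SE 0.087), and seed markers in 1 of 5 with 2 negative (camera adjusted p = 0.299). SGR1 did not pass (0.09, SE 0.081, adjusted p = 0.413).

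The interaction passed in 4382 genes with a positive and 4092 with a negative sign, 42.2% of those tested, and was at least 2-fold in 1506 and 855 of them. With library totals alone the counts were 3726 and 5225 (41.6% positive, against 51.7%). Solyc08g079890.2 (7.66, SE 0.353) and Solyc01g081250.3 (adjusted p = 2.05e-10) were among the largest outside the lists, the latter negative, with no count in wild type at breaker and at least 467-fold more after 7 days, against 84.7 ± 19.7 and 38.7 ± 1.72 CPM in slnor. Adjusted over the list alone, 6 lists differed by 1 gene each, namely carotenoid genes after lycopene (6 positive), carotenoid synthesis up to lycopene (4 positive), chlorophyll breakdown (1 negative), ethylene perception and response (3 negative), flavour volatiles (6 positive) and light harvesting (17 positive).

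The genotype effects at the 2 stages were then compared. Of the genes higher in slnor at breaker, 2815 were also higher 7 days later, against 1463 for independent lists of the same sizes, and of those lower at breaker 2628 were also lower, against 1303. Opposite calls were made for 717 and 853 genes, against 1408 and 1354 for independent lists, so 77.6% of the 7013 genes called at both stages had the same sign. Across all genes tested, which are not independent replicates, Pearson's r of the log2 fold changes was 0.249 and Spearman's rho 0.365. PG2a, TBG4, CEL2, LOXC, GGPS2, ACS2 and SGR1 were lower at both stages, ACO5, SUS1 and LOXD were higher at both, and CHS1, CHS2, MYB12, F3H, CER6, VDE and Cab-1A were lower at breaker and higher 7 days later.

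The stage changes of the genotypes were compared in the same way. Genes that rose in both numbered 3792 (1746 for independent lists) and genes that fell in both 3640 (1675), whereas 482 rose in wild type and fell in slnor and 575 did the reverse. Of the 8489 genes called in both, 87.6% had the same sign, and across genes Pearson's r was 0.473 and Spearman's rho 0.561. The median ratio of the slnor change to the wild-type change was 0.469 among the 6659 genes that rose in wild type (quartiles 0.099 and 0.833) and 0.419 among the 6449 that fell (quartiles 0.096 and 0.751). With library totals alone the medians were 0.295 and 0.530. Among genes called in slnor instead, the median ratio of the wild-type change to the slnor change was 1.03, or 0.961 with library totals alone. The interaction passed in 3601 of the genes that rose, and was negative in 3229 of them and positive in 372. Negative here means a smaller rise or a fall of any size in slnor, and positive a larger rise. Among those that fell, the interaction passed in 3757, and was positive in 3485 and negative in 272. Positive here means a smaller fall or a rise of any size in slnor, and negative a larger fall.

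The wild-type stage change was last set against the genotype effect 7 days after breaker. Of the genes that rose in wild type, 3466 (52.0%) were lower in slnor after 7 days, against 1824 for independent lists, and 1021 were higher, against 1895. Of those that fell, 3551 (55.1%) were higher in slnor, against 1835, and 769 were lower, against 1766. XYL1 and CEL2 were among the genes that rose and were lower in slnor, and RBCS-2A, PSBQ, F3H, LOXA, GBSS1 and GAME12 among those that fell and were higher. Both comparisons use the same 3 wild-type libraries, which alone gives a negative correlation. Pearson's r was −0.568 against a mean of −0.490 (−0.518 to −0.456) in 20 simulations of unchanged groups, Spearman's rho −0.494 against −0.430, and the covariance −1.15 against −0.094, a difference of −1.06. In the simulations 0 genes were called in both with opposite signs by edgeR, against 7017 here. With unchanged groups almost no calls can arise, so that count does not test the overlap. The 3 shared libraries cannot be split into parts of at least 2 libraries each, so part of the excess over independent lists may come from them.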

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

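All results in this part stand out because the genotype effect differed between the 2 stages by the interaction test, and the tests of flavonoid genes against scaling and against epidermis were chosen only after the result was seen. Groups of 3 libraries are too small for a test of single outlying samples. Of the 15 lists, 6 differed between stages (camera adjusted p, interaction): flavonoid and phenylpropanoid genes (3.80e-13), light harvesting (1.33e-08), cuticle (5.65e-08), ripening transcription factors (5.65e-08), cell wall softening (9.99e-05) and carotenoid steps after lycopene (0.00422). With an estimated correlation the last of these did not pass (adjusted p = 0.130), and the other 5 did (0.0158 to 0.0265). Of the 48 genes named for the genotype effects, 39 differed, with interaction log2 fold changes between 0.34 and 5.68 in size. Most of these genes were chosen by a large genotype effect at a stage in the same libraries, which favours such a difference. Among all genes tested the interaction passed in 42.2%.

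Most of these genes stood higher relative to wild type after 7 days than at breaker. In the flavonoid list the values were 3.85 for CHS1, 3.93 for CHS2, 4.51 for MYB12, 3.68 for F3H and 0.95 for PAL3. Cuticle genes CER6 and CD1 had 2.88 and 5.68. Among light-harvesting genes, Cab-3C, Cab-1A and RBCS-2A had 4.88, 2.95 and 1.14. Glycoalkaloid genes GAME11, GAME12 and GAME1 had 2.31, 2.89 and 2.74. Cell wall genes PG2a, MAN4a, TBG4 and CEL2 had 1.73, 3.49, 1.74 and 0.63. Among carotenoid genes, ZISO, VDE, BCH2 and LCY1 had 0.91, 1.89, 1.36 and 0.99. Transcription factor genes NOR, FUL1, AP2a and GLK2 had 0.46, 1.29, 0.82 and 2.71. The ethylene genes ACS2, E4 and E8 had 0.78, 0.55 and 0.39, the volatile genes LOXC and LOXA 1.54 and 1.97, the starch and sugar genes GBSS1 and SUS1 1.33 and 0.60, and NCED2 0.93. A smaller group moved the other way, with −3.52 for NAC1, −3.56 for XYL1, −1.12 for LOXD, −1.68 for AADC1A, −0.73 for CYP707A2 and −0.34 for GGPS2.

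The flavonoid pattern was weighed further, since its median changed sign between the stages. The tables argue against the scaling of the libraries as its cause. With RLE factors the medians were −1.94 at breaker and 1.12 after 7 days, and with library totals alone −1.76 and 1.21, so the value nearest 0 at breaker, −1.758, lay far from 0. A different share of epidermis in the fruit samples stays open and cannot be told apart from a change within cells. The 5 cuticle genes of at least 5 CPM moved the same way as the flavonoid genes, with medians of −1.18 and 1.52, and the difference between the lists, 0.751 at breaker and 0.41 after 7 days, was too small to exclude it. The other 3 of the 8 cuticle genes, all under 3 CPM at breaker (CD1 and GPAT6 among them), rose at breaker and are left out by that minimum. Over all 8 the medians were −0.70 and 1.98. The difference in genotype itself stays open too, and was not tested apart from the share of epidermis.

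The split of the samples was tested for the interaction by reassigning genotype within each stage. The real assignment called 8474 genes and was the only 1 of 100 to call so many, the highest of the others calling 3082. Such reassignment mixes wild type and slnor within a group, so the genotype effect itself adds to the spread and lowers the count. The test therefore cannot exclude a chance assignment of the libraries for that count.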

How the results depend on the processing

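Lists with checked names only, and lists under library totals alone, were tests chosen only after the data were seen. No named gene or list that passed changed direction under any alternative. With library totals alone the larger side of the interaction did switch, from 4382 positive and 4092 negative genes to 3726 and 5225. It also switched for the slnor stage change, from 5261 rising and 5212 falling to 3911 and 6754. The wild-type stage change went from 6659 rising and 6449 falling to 6471 and 6595. Other alternatives also switched a near-even split, such as RLE factors in the wild-type stage change (6464 and 6606). Medians of some lists that had not passed changed sign with library totals alone too, such as ethylene perception and response at breaker (−0.05 to 0.12) and carotenoid synthesis up to lycopene in the interaction (0.04 to −0.04). The counts of genes called kept within 1.5 times under RLE factors, both low-count filters, DESeq2, limma-voom, fits of only the groups compared (not run for the interaction, which needs all 12 libraries) and each library left out, where 88.29% to 99.1% of the calls of a comparison were kept. Nothing in the labels says that the replicate numbers pair the samples, and the values showed no sign of it. Deviations of the 18 same-numbered pairs correlated at −0.259 to 0.091, against −0.212 to 0.226 for pairs with other numbers. Of 12 libraries, 1 correlated best with its own number. These values do not exclude a shared plant, day or batch. With the replicate number as a block, 5043 and 4687 genes were higher and lower at breaker, 5625 and 5420 after 7 days, 6580 and 6358 in the wild-type stage change, 5168 and 5069 in the slnor stage change, and 4263 and 3981 in the interaction. The block took light-harvesting genes after 7 days from an adjusted p of 0.0588 to 0.048 and changed no other list call. Library totals alone moved the breaker counts to 8447 higher and 2836 lower, and took NOR at breaker to −0.061 (adjusted p = 0.281). By the alternative's construction, the lower share of the 100 most abundant genes in slnor then counts as a rise of the other genes. How much of the move this covers was not tested. An added 2-fold threshold left 1301 higher and 937 lower at breaker, 2005 and 925 after 7 days, 1406 and 2922 in wild type, 833 and 1743 in slnor and 1506 and 855 for the interaction, and 908, 1639 and 1683 shared genes in the 3 comparisons between effects. Of lists, an estimated correlation called 0 at breaker, 0 after 7 days, 2 in wild type and 0 in slnor, where the preset correlation called 8, 3, 5 and 2, and it kept 5 of 6 for the interaction. Fry, which asks only whether members move 1 way, called 14, 15, 14, 14 and 13. With checked names only, 5 lists were called at breaker and 4 in slnor, and fewer genes were tested. The chlorophyll breakdown and seed marker lists, with 1 and 0 checked names among their tested members, were too short for this check. The calls of AGPL1, CAB1B and Cab-1D at breaker, PAR2 after 7 days and PSY1 in wild type were lost under at least 1 alternative, and the cause was not tested. Depth limits genes near or under 1 CPM, among them CD1, GPAT6, GLK2, ACS3 and most chlorophyll a/b-binding genes.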

Other observations

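The tests of this part were written before their results were seen, but the reading of the chromosome test was changed afterwards, and the genes of this paragraph were chosen after their values were seen. Some genes of the cell wall list parted. While PG2a was far lower in slnor, PMEU1 (Solyc03g123630.4), a pectin methylesterase gene, was higher, with log2 fold changes of 1.005 at breaker (adjusted p = 1.25e-09) and 2.07 after 7 days (adjusted p = 3.16e-13). The fruit pectin methylesterase PE1 (Solyc07g064170.3) went from −0.29 at breaker to 0.80 after 7 days (interaction adjusted p = 4.79e-12). The pectate lyase gene PL (Solyc03g111690.4) and the expansin gene EXP1 (Solyc06g051800.3) differed far less than PG2a. They were at −0.21 and −0.34 at breaker and −0.20 and −0.52 after 7 days, beside −4.82 and −3.09 for PG2a. Ethylene synthesis genes also parted. ACS4 (Solyc05g050010.3) rose with stage by 1.74 in wild type and by 0.91 in slnor, whereas ACO1 (Solyc07g049530.3) fell by 1.34 and by 1.22 on the log2 scale.

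Among genes called in wild type, stage changes in slnor were smaller, with a median ratio of 0.469 for rising and 0.419 for falling genes. Choosing genes by their wild-type call lowers such a ratio and may account for part of it. Among genes called in slnor, the wild-type change was about equal to the slnor change (median ratio 1.029, or 0.961 with library totals alone), so the ratios above do not describe all genes. The choice alone would lower this reverse ratio in the same way, which argues against it as the whole cause. Under other scalings the highest median was 0.530, still under 0.7, so scaling alone does not account for the ratio. The split of the samples could not be judged for the 4 comparisons of 3 against 3, since 10 splits are too few for a share under 0.05. The real split, 1 of the 10, called 9574 genes at breaker, 11420 after 7 days, 12938 in wild type and 10334 in slnor, and the highest other split called 0 in each by edgeR.

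A mutant line may carry a stretch of chromosome from another background. For slnor, a CRISPR line, a cross that could bring one in was not checked. Other differences between the lines were not tested. Of the genes tested, 96 changed at least 8-fold the same way at both stages, 65 higher and 31 lower in slnor. Chromosome 7 held 14 of them, 14.6% against 7.5% of the genes tested (ratio 1.94, upper 95% bound 3.10), with the lowest adjusted p of the 12 chromosomes at 0.149 (binomial, one-sided). Chromosome 10, which carries NOR, held 4 (ratio 0.64). Before the result was seen, an adjusted p above 0.05 on every chromosome was to count against such a stretch. Missing the threshold does not exclude one, since the upper bound for chromosome 7 exceeds a 3-fold excess, and the question stays open.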
